A study of Mus musculus with 20 samples.

How the data were processed

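Per the labels, biotin-labelled RNA of the sorted cells was hybridized to expression arrays. The authors' deposited series table holds log2 of the normalized array signal for 24539 probe sets, from 3.28 to 13.63. The authors' deposited filtered table holds the same values as linear intensity for 12440 probe sets, whose log2 differed from the series table by at most 0.0075. The authors' normalization method, scanner and summarisation software are not given in the sources used here. The authors' filter was not described either. All 11833 probe sets whose 4 arrays of some group reached an intensity of 100 were in the filtered table, and 607 others were too. The authors' deposited comparison tables give, per the file headers, a log2 difference, a p-value and a q-value for 5 pairs of groups. Those log2 differences were within 0.0084 of the differences of group means in the series table. Whether background was subtracted is not known and no detection call was available, so differences at low signal may be compressed.

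The analysis used the log2 values of the probe sets in the authors' deposited filtered table. Of these, 83 had no gene symbol and were left out. For the 2431 genes with several probe sets the 1 with the highest mean over the 20 arrays stood for the gene, beside 6698 genes with 1, so 9129 genes were tested. Probe sets of 1 gene were called in opposite directions for 19 genes in SL against DN and for Ncam1 in B against A, and for none in the other main pairs. Gene symbols are those of the files, 8766 of them current in the mouse RefSeq annotation and 317 found there as synonyms. Chromosome positions are those of the deposited comparison tables, which do not name the genome build. Of 8403 of their genes found by symbol in the GRCm38.p6 annotation, 8399 overlapped the gene of that symbol.

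Groups were compared in R 4.3.3 with limma 3.58.1, in 1 linear model with a mean per group over all 20 arrays, 15 residual degrees of freedom and moderated variances (4.34 prior degrees of freedom). The median residual SD was 0.183 log2 units, and arrays of a group correlated across genes at r = 0.951 to 0.983. Tests were two-sided, with Benjamini-Hochberg adjustment over the 9129 genes for each contrast and a threshold of adjusted p under 0.05. The contrasts were the 5 pairs of the deposited comparison tables, the other 5 pairs, the average difference along each PDGF receptor and their interaction. The groups, contrasts, gene lists, rule for named genes and alternatives were fixed before the data were examined, apart from 4 alternatives named with the sensitivity results. The labels do not state that replicates are separate animals or sorts, so p-values measure only the spread between these arrays. Arrays of the same replicate number were compared through their residuals from the group means, by correlation across genes. Every number correlated above 0.1 only for AB with A (r = 0.185 to 0.398) and AB with B (r = 0.17 to 0.422), so the replicate number was also fitted as a block.

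36 lists of genes of bone, cartilage, stromal, vessel, nerve, muscle and blood cell types and of pathways were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over all 180 tests of lists in the main pairs. 72 tests passed, 39 upward and 33 downward, and no called list had a median and a mean of opposite sign to its test. With a correlation estimated per list 3 calls held, those of the marrow stromal reticular list for AB against A and AB against B and of the blood niche factor list for AB against B. Limma's fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, called 96. Lists share members, such as Cxcl12, Kitl and Vcam1 in the stromal and niche lists.

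The rule for named genes took, for each main pair, the 8 genes with the largest difference in each direction among those past the threshold whose arrays did not overlap, without genes named only by a clone or prediction. 2 genes that met it are not reported here. It added the sorted surface markers, up to 4 members of each list with the largest difference, and the 6 largest for each group's highest genes, for the receptor averages and for the interaction. Uchl5, Ctsk, Ckb and the gate transcripts' differences outside the main pairs were named after their values were seen. In a self-test on A and DN, arrays were simulated from each gene's mean and spread, with known differences added to randomly chosen genes. The model called 49.2% of genes changed by log2 0.5, 92.5% of those changed by 1 and 98.5% of those changed by 2. Of 167 calls, 7 fell on genes that had not been changed. The authors' deposited tables were not used for any fold or call of the report except in sentences that name them.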

Results

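The series holds expression arrays of osteoblastic cells sorted from enzymatically digested bone of untreated male C57BL6 mice aged 8 weeks. The sort left out cells with blood lineage markers and the endothelial marker CD31, and kept cells with CD51, the integrin alpha-v chain carried by bone-forming cells. It then divided the cells by Sca-1 and both PDGF receptors into 5 groups of 4 arrays each. Among Sca-1-negative cells, A carried PDGFRa alone, B carried PDGFRb alone, AB carried both receptors, and DN was negative for PDGFRa and is named for a double-negative state. SL held cells with low Sca-1 and no PDGFRa. The titles of DN and SL write the PDGFRb gate in a way that leaves its sign unclear, so DN is treated as negative for both receptors on the strength of its code alone. The 20 arrays carried 24539 probe sets, and array medians lay between log2 6.40 and 6.46. Differences are log2 ± SE from limma with n = 4 arrays per group, levels are mean log2 signal ± SD, and the number of arrays limits their precision.

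Transcripts of the sorted surface proteins were compared first. Pdgfra was at 7.87 ± 0.30 (SD, n = 4) in DN, 9.01 ± 0.10 in A, 9.72 ± 0.12 in AB, 9.03 ± 0.42 in B and 10.24 ± 0.11 in SL. It was higher in A than in DN by 1.14 ± 0.16 (adjusted p = 0.000318) and in AB than in B by 0.70 ± 0.16 (adjusted p = 0.0307). B and SL, both gated as PDGFRa-negative, exceeded DN by 1.16 ± 0.16 (adjusted p = 7.76e-06) and 2.37 ± 0.16 (adjusted p = 6.8e-10). B and A did not differ detectably in mean Pdgfra (log2 0.02 ± 0.16, 95% interval -0.32 to 0.36, adjusted p = 0.948). B replicates 1 and 2 lay below every A array, 3 and 4 above. Pdgfrb was at 8.78 ± 0.12 in DN and 9.27 ± 0.11 in A, against 10.56 ± 0.31 in B, 10.62 ± 0.11 in AB and 10.21 ± 0.07 in SL. It was higher in B than in A by 1.29 ± 0.12 (adjusted p = 1.37e-07), in AB than in A by 1.35 ± 0.12 (adjusted p = 4.08e-08) and in A than in DN by 0.49 ± 0.12 (adjusted p = 0.0244). Itgav, which encodes CD51, lay between 9.79 ± 0.16 in B and 10.05 ± 0.18 in DN. The Pdgfra difference between AB and B was not called without any 1 of B replicates 1 and 2 or AB replicates 1, 2 and 3 (adjusted p 0.0958 to 0.124). The Pdgfrb difference between A and DN was not called without any 1 of DN replicate 3 or A replicates 1 and 4 (adjusted p 0.0743 to 0.0816).

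Ly6a, which encodes Sca-1, was at 10.51 ± 0.21 in SL against 7.53 ± 0.54 in DN, a difference of 2.98 ± 0.72 (adjusted p = 0.00206). Within B its replicates 1 to 4 read 7.01, 7.10, 10.18 and 10.90, and within AB 7.09, 7.24, 8.72 and 10.05, although both groups were gated as Sca-1-negative. The SL arrays lay between 10.30 and 10.78, so B replicate 4 exceeded every SL array. Ptprc, which encodes the pan-leukocyte marker CD45, was at 8.63 ± 0.71 in B and 7.05 ± 1.17 in DN, and was higher in B than in DN by 1.58 ± 0.56 (adjusted p = 0.0277) and than in SL by 1.74 ± 0.56 (adjusted p = 0.0485). It passed in none of the 5 main pairs (lowest adjusted p = 0.237, for B against A, and 0.0389 with the replicate number as a block). With each array's neutrophil list score as a covariate the differences turned to -0.35 and -0.15 (adjusted p = 0.402 and 0.857), and with replicates 1 and 2 alone in B and AB the calls ended (adjusted p = 0.152 and 0.235). Both settings, and that without every replicate 4, were chosen after the data were seen. Pecam1, which encodes CD31, was at most 7.03 ± 0.40, in B, and passed in no main pair either. The call of Ptprc was lost for B against DN without any 1 of DN replicates 2 and 3 or B replicates 1 and 4 (adjusted p 0.062 to 0.113). That for B against SL was lost without any 1 of B replicates 1, 3 and 4 or SL replicates 1, 2 and 3 (adjusted p 0.0775 to 0.179).

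**Figure D1:**
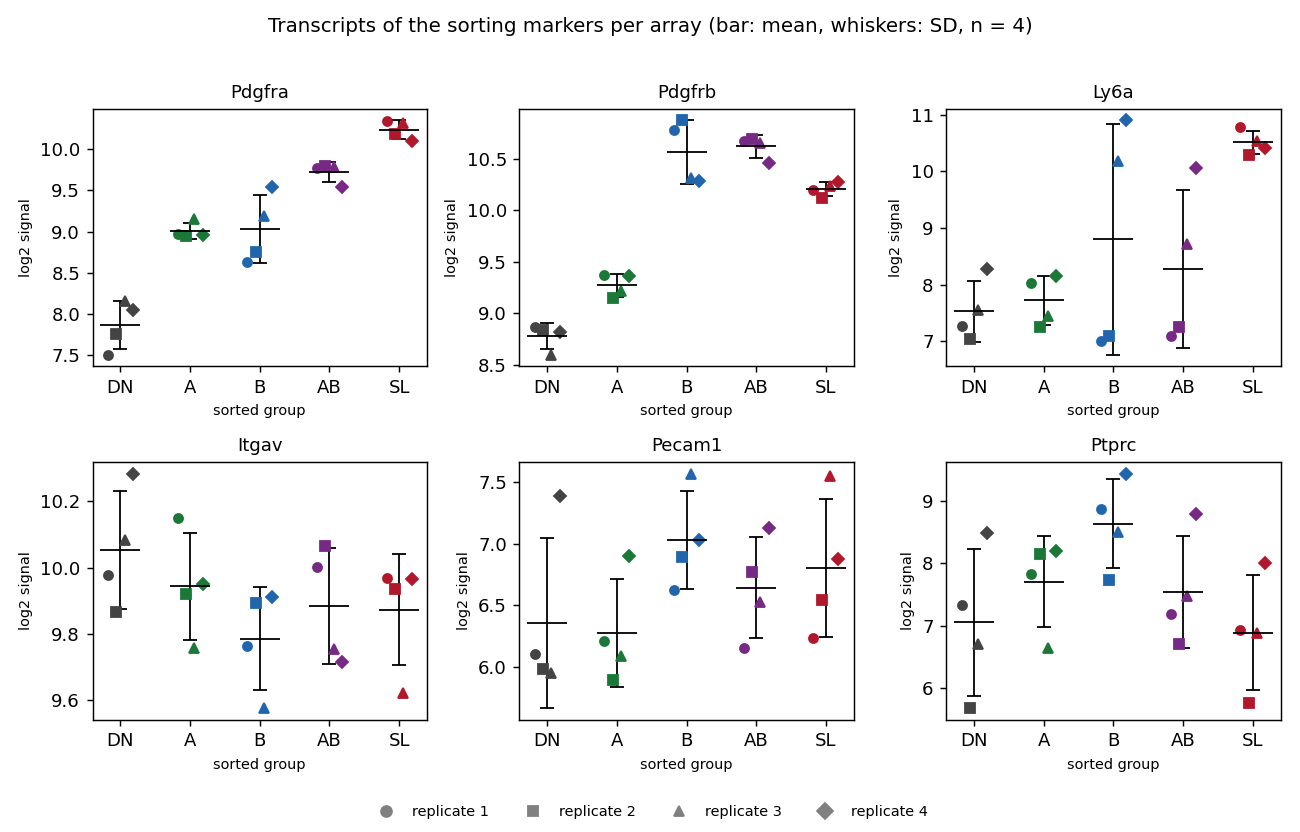
Log2 signal of the sorted surface proteins' transcripts in each of the 20 arrays (points) with group means (bars), by group on the horizontal axis. Ly6a of B replicates 3 and 4 reads 10.18 and 10.90, beside 10.30 to 10.78 in SL, while replicates 1 and 2 read 7.01 and 7.10.

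Among 9129 genes tested, 4620 differed among the 5 groups by limma's moderated F test with Benjamini-Hochberg adjustment. The first principal component carried 56.3% of the variance and placed DN between -43.5 and -40.2 and A between -28.9 and -23.4. On it B lay between 15.1 and 26.5, AB between 23.6 and 31.6 and SL between 17.9 and 22.2. The second component, with 12.2%, set SL (between -26.3 and -18.4) apart from B and AB, whose lowest score was 4.

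**Figure D2:**
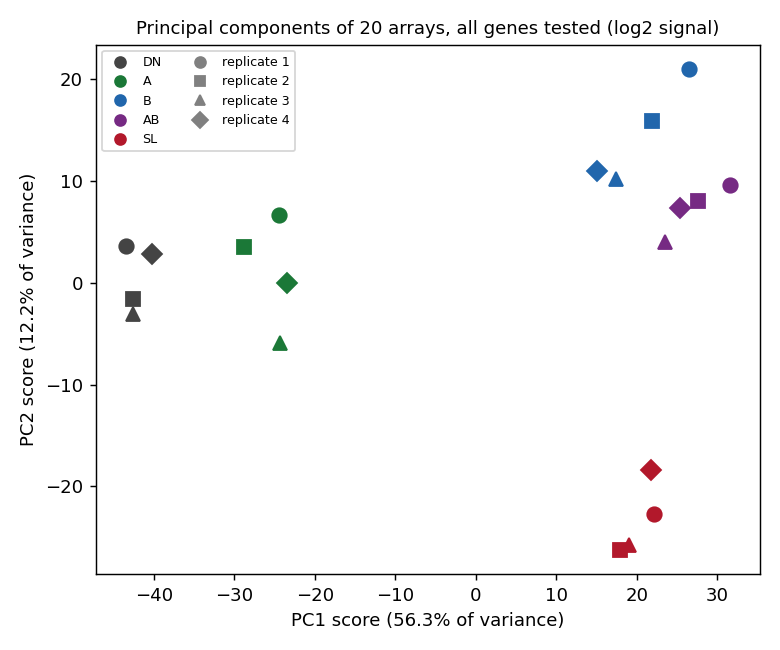
Scores of the 20 arrays on the first and second principal components of 9129 genes, coloured by group. DN and A lie on the negative side of the first component, and SL lies below -18.4 on the second, under B and AB.

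A and DN differ in the PDGFRa gate, which asks what PDGFRa marks among cells without PDGFRb. In all, 322 genes differed, 264 higher and 58 lower in A. Gpc3, a cell-surface heparan sulfate proteoglycan (chromosome X, 52272426 to 52613950), rose from 8.06 ± 0.35 in DN to 10.33 ± 0.35 in A, a difference of 2.27 ± 0.22 (adjusted p = 7.73e-06). Apod, a lipid-binding lipocalin, was higher by 2.26 ± 0.22, the complement protease gene C1s1 by 2.14 ± 0.30, the carbonic anhydrase gene Car3 by 2.05 ± 0.20 and the iron carrier transferrin, Trf, by 2.03 ± 0.19 (adjusted p at most 0.00031). The ferritin receptor gene Scara5 was higher by 1.97 ± 0.52 (adjusted p = 0.0391), the dipeptidase gene Dpep1 by 1.93 ± 0.28 and the carboxypeptidase gene Cpz by 1.88 ± 0.21. Falls were smaller. Agbl4, a tubulin-trimming carboxypeptidase, fell by 1.55 ± 0.28 (adjusted p = 0.00333), and the alpha-1-antitrypsin gene Serpina1a fell by 1.14, the bradykinin receptor gene Bdkrb1 by 0.93, Zim1 by 0.83, Prss50 by 0.82, Muc1 by 0.80, Gnat2 by 0.79 and Nckap5 by 0.76. Serpina1a belongs to a family of near-identical genes whose probe sets need not tell members apart.

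Several of these calls rested on single arrays. The call of Gnat2 was lost without A replicate 4 (adjusted p = 0.0516) and that of Bdkrb1 without A replicate 4 (adjusted p = 0.0523). The call of Scara5 was lost without any 1 of DN replicates 1 and 2 or A replicates 1, 2, 3 and 4 (adjusted p 0.0722 to 0.122), and that of Prss50 without any 1 of DN replicates 1 and 2 or A replicates 1 and 4 (adjusted p 0.0534 to 0.073). Serpina1a missed the threshold without any 1 of DN replicates 1, 2, 3 and 4 or A replicates 1, 2 and 4 (adjusted p 0.0532 to 0.122), Muc1 without any 1 of DN replicates 1, 2, 3 and 4 or A replicates 2, 3 and 4 (adjusted p 0.0532 to 0.101) and Zim1 without any 1 of DN replicates 2 and 4 or A replicates 1, 3 and 4 (adjusted p 0.0532 to 0.123). The whole count came to 179 without A replicate 4, 196 without A replicate 1, 192 without every replicate 4, 167 with these 2 groups alone and 546 with the replicate block. Nckap5 did not pass without every replicate 4 (adjusted p = 0.0965) or with these 2 groups alone (0.0595).

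Lists of marrow stroma and bone were higher in A. A list is called as a set, with the adjusted p of limma's camera and the median log2 difference of its members. For each list without a second count, that adjusted over the list alone was the same. With a correlation estimated per list, 3 of the 72 list calls held, all in AB, so each list's value stands beside it. Marrow stromal reticular genes were higher in A (median log2 0.56, adjusted p = 1.45e-13, 0.0591 with estimated correlation). Of 24 measured, 11 were higher (13 higher over the list alone), led by Cxcl12 (log2 1.54), Adipoq (1.44, adjusted p 0.0746 without every replicate 4), Lepr (1.28) and Serping1 (1.21). Blood niche factor genes were higher in A (median log2 0.33, adjusted p = 1.02e-05, 0.0693 with estimated correlation). Of 19 measured, 4 were higher (9 higher over the list alone), led by Cxcl12 (log2 1.54) and Igf1 (1.09). Adipocyte genes were higher in A (median log2 0.26, adjusted p = 7.89e-05, 0.0883 with estimated correlation). Of 9 measured, without Pparg, Fabp4, Plin1 or Cidec among them, 3 were higher, led by Ebf2 (log2 1.87) and Adipoq (1.44, adjusted p 0.0746 without every replicate 4). Mature osteoblast genes were higher in A (median log2 0.08, adjusted p = 0.0137, 0.237 with estimated correlation). Of 17 measured, 4 were higher (5 higher and 1 lower over the list alone), led by Car3 (log2 2.05) and Slc36a2 (1.14). Osteocyte genes were higher in A (median log2 0.30, adjusted p = 0.00209, 0.0591 with estimated correlation). Of 12 measured, without Sost, Mepe, Phex or Fgf23 among them, 3 were higher (6 higher over the list alone), led by Dmp1 (log2 1.00) and Kcnk2 (0.70). Wnt pathway genes were higher in A (median log2 0.25, adjusted p = 0.01, 0.0883 with estimated correlation). Of 22 measured, 3 were higher (7 higher and 2 lower over the list alone), led by Sfrp4 (log2 0.84). Calls of some members ended when 1 array was left out, that of Lepr without any 1 of DN replicates 1 and 2 or A replicates 1, 3 and 4 (adjusted p 0.0559 to 0.113), of Dmp1 without any 1 of DN replicates 2 and 4 or A replicates 1, 2 and 3 (adjusted p 0.0516 to 0.0802), of Kcnk2 without any 1 of DN replicate 3 or A replicates 1 and 2 (adjusted p 0.0511 to 0.0699) and of Sfrp4 without any 1 of DN replicates 1, 2 and 3 or A replicates 1, 2 and 4 (adjusted p 0.0518 to 0.148).

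Matrix and fibroblast lists were higher too. Collagen matrix genes were higher in A (median log2 0.13, adjusted p = 0.00314, 0.25 with estimated correlation). Of 30 measured, 6 were higher (11 higher over the list alone), led by Adamts2 (log2 0.91). Tendon and periosteum genes were higher in A (median log2 0.10, adjusted p = 0.00314, 0.292 with estimated correlation). Of 19 measured, 2 were higher (4 higher over the list alone), led by Angptl7 (log2 1.51). Osteoclast regulator genes were higher in A (median log2 0.29, adjusted p = 0.000616, 0.0568 with estimated correlation). Of 18 measured, 1 was higher (7 higher over the list alone). Sca-1-positive fibroblast genes were higher in A (median log2 0.55, adjusted p = 1.45e-06, 0.304 with estimated correlation). Of 20 measured, 4 were higher (10 higher over the list alone), led by Cd34 (log2 2.08, adjusted p = 0.1, but 0.0275 with the replicate block, 0.000529 with B and AB from replicates 1 and 2 and 0.00892 with these 2 groups alone). Chondrocyte genes were lower in A (median log2 -0.17, adjusted p = 0.00927, 0.551 with estimated correlation). Of 21 measured, none passed, led by Ihh (log2 -0.83, adjusted p = 0.174) and Epyc (-0.80, adjusted p = 0.293, but 0.0162 with B and AB from replicates 1 and 2). Schwann cell genes were lower in A (median log2 -0.20, adjusted p = 0.0461, 0.547 with estimated correlation), a call lost without any 1 of DN replicates 1 and 3 or A replicates 1, 2 and 4 (adjusted p 0.0505 to 0.183), and adjusted p = 0.0521 with quantile normalization and 0.0798 without every replicate 4. Of 11 measured, none passed, including Mbp (log2 -0.52, adjusted p = 0.507).

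The neutrophil and monocyte lists were also higher in A than in DN. Neutrophil lineage genes were higher in A (median log2 0.62, adjusted p = 0.000115, 0.454 with estimated correlation, 0.959 with the neutrophil covariate by construction). Of 17 measured, none passed, led by Fcnb (log2 0.91, adjusted p = 0.285, but 0.0105 with the replicate block and 0.00957 without every replicate 4) and Elane (0.87, adjusted p = 0.387). Monocyte and macrophage genes were higher in A (median log2 0.49, adjusted p = 0.0158, 0.53 with estimated correlation), a call lost without any 1 of DN replicates 1, 2 and 3 or A replicate 4 (adjusted p 0.0547 to 0.0764), and adjusted p = 0.235 at median log2 -0.15 with the neutrophil covariate. Of 9 measured, 1 was higher, led by Vcam1 (log2 0.93). Osteoclast genes were higher in A (median log2 0.41, adjusted p = 0.0148, 0.0939 with estimated correlation), but adjusted p = 0.165 with the neutrophil covariate. Of 8 measured, 2 were higher. Interferon response genes were higher in A (median log2 0.26, adjusted p = 0.0121, 0.304 with estimated correlation), but adjusted p = 0.237 with the neutrophil covariate. Of 14 measured, 2 were higher (4 higher over the list alone). Among the monocyte and osteoclast lists the members that passed were the stromal adhesion molecule gene Vcam1, the collagen-degrading protease gene Ctsk and the creatine kinase gene Ckb, whose calls ended when 1 array was left out for Vcam1 (without any 1 of DN replicates 1, 2 and 3 or A replicates 1, 2 and 4 (adjusted p 0.0705 to 0.171)) and Ckb (without any 1 of DN replicates 1, 2 and 3 or A replicates 1, 2, 3 and 4 (adjusted p 0.0505 to 0.113)). The neutrophil list score of the DN arrays 1 to 4 was -0.39, -0.95, -0.82 and 0.27, and that of the A arrays 0.19, 0.28, -0.34 and 0.57. In all, 16 of the 36 gene lists were called in this pair. Other settings also called pericyte and smooth muscle (median log2 0.07, adjusted p = 0.339, but 0.0252 with the neutrophil covariate), erythroid (median log2 0.28, adjusted p = 0.314, but 0.0462 without DN replicate 4, 0.0262 with the replicate block, 0.0285 without every replicate 4 and 0.0416 at median log2 -0.23 with the neutrophil covariate), B lineage (median log2 0.35, adjusted p = 0.195, but 0.0462 without DN replicate 4 and 0.0331 without every replicate 4), blood stem and progenitor (median log2 0.36, adjusted p = 0.0926, but 0.0295 without DN replicate 4, 0.022 with the replicate block, 0.017 with B and AB from replicates 1 and 2 and 0.00788 without every replicate 4), cell cycle (median log2 0.09, adjusted p = 0.423, but 0.00375 at median log2 -0.17 with the neutrophil covariate), tissue dissociation response (median log2 -0.10, adjusted p = 0.106, but 0.0286 to 0.0416 without any 1 of DN replicate 2 or A replicates 3 and 4, 0.0474 with the replicate block, 0.0376 with B and AB from replicates 1 and 2 and 0.00244 with the neutrophil covariate) and glycolysis (median log2 -0.11, adjusted p = 0.0675, but 0.0189 to 0.0398 without A replicate 3 or 4, 0.0364 with B and AB from replicates 1 and 2, 0.0168 without every replicate 4 and 0.00733 with the neutrophil covariate).

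SL and DN differ in Sca-1, but Pdgfrb was also higher in SL (log2 1.43), so the pair does not isolate Sca-1. 4122 genes differed (2180 higher, 1942 lower in SL). The pannexin channel gene Panx3 fell by 5.28 ± 0.31 (adjusted p = 9.95e-11), from 10.21 ± 0.19 to 4.94 ± 0.40, the growth plate collagen Col10a1 (chromosome 10, 34389981 to 34397085) by 5.08, the cartilage proteoglycan epiphycan, Epyc, by 4.75 and the growth plate kinase gene Prkg2 by 4.67. Serpina1a fell by 4.94, the sodium pump regulator Fxyd2 by 4.77 and the potassium channel gene Kcna1 by 4.56 (adjusted p at most 6.49e-05 for these genes). In SL, Clec3b, which encodes tetranectin (chromosome 9, 123150946 to 123157430), rose by 4.33 ± 0.61 (adjusted p = 8.32e-06), and Aldh1a2, an enzyme of retinoic acid synthesis, by 4.14 ± 0.49. C1s1 rose by 4.13 ± 0.30, Ms4a4d by 4.12 ± 0.41, the cytochrome gene Cyp2f2 by 4.04 ± 0.29, Dpep1 by 4.04 ± 0.28 and the progenitor marker Cd34 by 4.01 ± 0.67. Uchl5, a deubiquitinase, had the largest fitted rise, 5.10 ± 1.53 (adjusted p = 0.0104). Its SL arrays read between 8.04 and 10.55, while the A arrays read 3.83, 4.05, 10.08 and 9.74.

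Osteoblast maturation, cartilage and nerve-sheath lists were lower in SL. Chondrocyte genes were lower in SL (median log2 -1.93, adjusted p = 1.87e-11, 0.164 with estimated correlation). Of 21 measured, 19 were lower, led by Col10a1 (log2 -5.08) and Epyc (-4.75). Schwann cell genes were lower in SL (median log2 -2.16, adjusted p = 2.51e-08, 0.121 with estimated correlation). Of 11 measured, 10 were lower, including Mbp (log2 -3.81). Mature osteoblast genes were lower in SL (median log2 -1.24, adjusted p = 1.46e-06, 0.0568 with estimated correlation). Of 17 measured, 1 was higher and 13 lower, led by Slc13a5 (log2 -3.43) and Smpd3 (-3.07). Cell cycle genes were lower in SL (median log2 -0.73, adjusted p = 0.00013, 0.426 with estimated correlation). Of 22 measured, 15 were lower (18 lower over the list alone), led by Top2a (log2 -1.51) and Rrm2 (-1.34). Tissue dissociation response genes were lower in SL (median log2 -0.64, adjusted p = 2.01e-07, 0.362 with estimated correlation). Of 26 measured, 1 was higher and 20 lower (1 higher and 22 lower over the list alone), led by Egr2 (log2 -1.95). Glycolysis genes were lower in SL (median log2 -0.62, adjusted p = 6.36e-05, 0.209 with estimated correlation). Of 13 measured, 9 were lower, led by Hk2 (log2 -1.93). Skeletal muscle genes were lower in SL (median log2 -1.37, adjusted p = 0.0261, 0.121 with estimated correlation). Of 3 measured, 2 were lower, led by Tnni2 (log2 -2.78) and Tnnt3 (-1.37).

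Fibroblast and stromal lists were higher. Sca-1-positive fibroblast genes were higher in SL (median log2 2.46, adjusted p = 1.4e-07, 0.271 with estimated correlation). Of 20 measured, 17 were higher and 1 lower (17 higher and 2 lower over the list alone), led by Clec3b (log2 4.33), Cd34 (4.01), Mfap5 (3.83) and Tnxb (3.41). Marrow stromal reticular genes were higher in SL (median log2 0.66, adjusted p = 6.92e-05, 0.25 with estimated correlation). Of 24 measured, 15 were higher and 2 lower (15 higher and 3 lower over the list alone), led by Fst (log2 2.77), Serping1 (2.46) and Angpt1 (2.31). Blood niche factor genes were higher in SL (median log2 0.62, adjusted p = 0.0424, 0.304 with estimated correlation), a call lost without DN replicate 3 (adjusted p = 0.0722). Of 19 measured, 12 were higher and 4 lower (12 higher and 5 lower over the list alone), led by Bmp4 (log2 3.17) and Igf1 (2.62). Collagen matrix genes were higher in SL (median log2 0.26, adjusted p = 0.0344, 0.383 with estimated correlation). Of 30 measured, 17 were higher and 6 lower (17 higher and 8 lower over the list alone), led by Eln (log2 3.04) and Adamts2 (1.91). Tendon and periosteum genes were higher in SL (median log2 0.29, adjusted p = 0.0338, 0.423 with estimated correlation), but adjusted p = 0.0705 without every replicate 4. Of 19 measured, 9 were higher and 1 lower, led by Angptl7 (log2 2.10) and Ptn (1.68). Interferon response genes were higher in SL (median log2 0.42, adjusted p = 0.0165, 0.322 with estimated correlation). Of 14 measured, 7 were higher, led by Gbp2 (log2 2.19). Blood stem and progenitor genes were higher in SL (median log2 0.59, adjusted p = 0.0412, 0.353 with estimated correlation), a call lost without DN replicate 1 or SL replicate 4 (adjusted p 0.0634 to 0.095). Of 10 measured, 6 were higher, led by Cd34 (log2 4.01) and Procr (2.02). Cd34 and the endothelial protein C receptor gene Procr, which led the progenitor list, are also carried by fibroblasts and vessels, and Cd34 stands in the Sca-1-positive fibroblast list as well. In all, 14 lists were called in this pair, and other settings also called erythroid (median log2 -0.43, adjusted p = 0.108, but 0.0304 without SL replicate 4, 0.022 with the replicate block, 0.0323 without every replicate 4 and 0.0313 with the neutrophil covariate).

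AB and A differ in the PDGFRb gate among PDGFRa-positive cells. In all, 3004 genes differed (1612 higher, 1392 lower in AB). Adipoq, which encodes the hormone adiponectin (chromosome 16, 23146536 to 23158028), rose from 5.85 ± 0.43 in A to 10.44 ± 0.43 in AB, a difference of 4.58 ± 0.29 (adjusted p = 1.04e-09). Kitl, which encodes stem cell factor, rose by 2.93 ± 0.16, the lymphatic growth factor gene Vegfc by 2.95 ± 0.18 and Esm1, a secreted proteoglycan, by 3.77 ± 0.21. The protease inhibitor gene Serpina3g rose by 3.95 ± 0.19, the phosphodiesterase gene Gdpd2 by 3.21 ± 0.23, the anion exchanger gene Slc26a7 by 3.14 ± 0.19 and the synapse organizer gene Cbln1 by 2.98 ± 0.23 (adjusted p at most 6.9e-09). Col10a1 fell by 5.26 ± 0.85 (adjusted p = 6.79e-05), Serpina1b by 5.11, Epyc by 4.39, Serpina1a by 4.21, Panx3 by 4.04, Fxyd2 by 4.03, Prkg2 by 3.91 and the chondrogenesis-associated gene Scrg1 by 3.90.

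The stromal lists rose together in AB. Marrow stromal reticular genes were higher in AB (median log2 2.00, adjusted p = 8.21e-20, 0.0266 with estimated correlation). Of 24 measured, 23 were higher, led by Adipoq (log2 4.58), Esm1 (3.77), Gdpd2 (3.21) and Kitl (2.93). Blood niche factor genes were higher in AB (median log2 1.20, adjusted p = 2.94e-05, 0.0792 with estimated correlation). Of 19 measured, 13 were higher and 3 lower, led by Kitl (log2 2.93) and Cxcl12 (2.71). Interferon response genes were higher in AB (median log2 0.52, adjusted p = 0.00104, 0.209 with estimated correlation). Of 14 measured, 9 were higher (10 higher over the list alone), led by Gbp2 (log2 1.31). Tendon and periosteum genes were higher in AB (median log2 0.69, adjusted p = 0.000537, 0.237 with estimated correlation). Of 19 measured, 13 were higher and 3 lower, led by Kera (log2 2.14) and Chodl (1.90). Adipocyte genes were higher in AB (median log2 0.23, adjusted p = 0.039, 0.304 with estimated correlation), a call lost without AB replicate 3 or 4 (adjusted p 0.0502 to 0.0601), and adjusted p = 0.0626 with the replicate block, 0.149 at median log2 -0.08 with B and AB from replicates 1 and 2 and 0.0757 without every replicate 4. Of 9 measured, 4 were higher, led by Adipoq (log2 4.58) and Lpl (2.06). Pericyte and smooth muscle genes did not pass (median log2 0.92, adjusted p = 0.0926, 0.625 with estimated correlation), but adjusted p = 0.0241 with the replicate block and 0.0114 with B and AB from replicates 1 and 2. Of 14 measured, 8 were higher and 3 lower, led by Rgs5 (log2 2.04), Abcc9 (1.92) and Ndufa4l2 (-1.67). Ribosomal protein genes did not pass (median log2 -0.18, adjusted p = 0.0507, 0.566 with estimated correlation), but passed without any 1 of A replicates 2 and 3 or AB replicates 1 and 4 (adjusted p 0.0135 to 0.0441), and adjusted p = 0.0474 with the replicate block and 0.0336 without every replicate 4. Of 13 measured, 2 were lower.

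Growth plate and nerve-sheath lists were lower in AB. Chondrocyte genes were lower in AB (median log2 -2.30, adjusted p = 1.59e-17, 0.0883 with estimated correlation). Of 21 measured, 20 were lower, led by Col10a1 (log2 -5.26) and Epyc (-4.39). Schwann cell genes were lower in AB (median log2 -2.41, adjusted p = 1.01e-10, 0.0883 with estimated correlation). Of 11 measured, 11 were lower, including Ncmap (log2 -3.18) and Erbb3 (-2.80). Mature osteoblast genes were lower in AB (median log2 -0.64, adjusted p = 6.05e-05, 0.0792 with estimated correlation). Of 17 measured, 2 were higher and 11 lower, led by Slc13a5 (log2 -2.93) and Smpd3 (-2.59). Tissue dissociation response genes were lower in AB (median log2 -0.65, adjusted p = 3.26e-10, 0.283 with estimated correlation). Of 26 measured, 23 were lower (24 lower over the list alone), led by Egr2 (log2 -1.36). Glycolysis genes were lower in AB (median log2 -0.77, adjusted p = 1.57e-07, 0.0939 with estimated correlation). Of 13 measured, 10 were lower (11 lower over the list alone), led by Hk2 (log2 -1.76). Cell cycle genes were lower in AB (median log2 -0.60, adjusted p = 3.43e-05, 0.404 with estimated correlation). Of 22 measured, 13 were lower (15 lower over the list alone), led by Cdk1 (log2 -1.27). Skeletal muscle genes were lower in AB (median log2 -1.32, adjusted p = 0.0148, 0.0939 with estimated correlation). Of 3 measured, 2 were lower, led by Tnni2 (log2 -2.42) and Tnnt3 (-1.32). The chondrocyte score of AB replicates 1 to 4 was -1.62, -1.28, -0.81 and -0.67.

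The list of Sca-1-positive fibroblasts moved with Ly6a across the arrays of B and AB. Sca-1-positive fibroblast genes were higher in AB (median log2 0.67, adjusted p = 0.0259, 0.596 with estimated correlation), a call lost without AB replicate 4 (adjusted p = 0.114), and adjusted p = 0.323 with B and AB from replicates 1 and 2 and 0.0565 without every replicate 4. Of 20 measured, 9 were higher and 3 lower (10 higher and 3 lower over the list alone), led by Pcolce2 (log2 -2.33) and Thy1 (1.78). Sca-1-positive fibroblast genes were higher in B (median log2 0.80, adjusted p = 0.0118, 0.552 with estimated correlation), a call lost without B replicate 4 (adjusted p = 0.137), and adjusted p = 0.875 with B and AB from replicates 1 and 2, 0.0565 without every replicate 4 and 0.108 with the neutrophil covariate. Of 20 measured, 11 were higher and 3 lower (12 higher and 3 lower over the list alone), led by Thy1 (log2 2.16), Pcolce2 (-1.81) and Cd248 (1.56). The list's score in AB replicates 1 to 4 was -0.06, -0.29, 0.18 and 0.75, and in B -0.32, -0.46, 0.64 and 0.96. In all, 13 lists were called for AB against A and 12 for B against A.

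B and A each carry 1 of the PDGF receptors. In all, 2714 genes differed (1377 higher, 1337 lower in B). Kcnj8 (chromosome 6, 142564837 to 142571614) and Abcc9, the channel and receptor subunits of the potassium channel of pericytes, rose by 3.47 ± 0.28 and 2.81 ± 0.33 (adjusted p = 3.75e-08 and 1.92e-06), and the pericyte signalling regulator gene Rgs5 rose by 3.36 ± 0.38. Kera, which encodes the tendon and cornea proteoglycan keratocan, rose by 3.09 ± 0.29, the pentraxin gene Ptx4 by 3.23 ± 0.28, chondrolectin, Chodl, by 2.75 ± 0.19, the activin-binding protein follistatin, Fst, by 2.66 ± 0.19 and Gas2 by 2.44 ± 0.20. Col10a1 fell by 3.51 ± 0.85 (adjusted p = 0.00358), Serpina1b by 3.30, Epyc by 3.29, Serpina1a by 3.20 and Prkg2 by 2.97. The calmodulin-like gene Calml3 fell by 2.91, Scrg1 by 2.86 and Lgr6, a receptor for R-spondins, by 2.85.

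Vessel-wall, tendon and stromal lists were higher in B. Pericyte and smooth muscle genes were higher in B (median log2 1.48, adjusted p = 5.06e-05, 0.289 with estimated correlation). Of 14 measured, 11 were higher and 2 lower, led by Kcnj8 (log2 3.47), Rgs5 (3.36), Abcc9 (2.81) and Notch3 (2.36). Tendon and periosteum genes were higher in B (median log2 0.80, adjusted p = 1.06e-06, 0.0939 with estimated correlation). Of 19 measured, 13 were higher and 2 lower, led by Kera (log2 3.09) and Chodl (2.75). Marrow stromal reticular genes were higher in B (median log2 0.86, adjusted p = 3.23e-07, 0.133 with estimated correlation). Of 24 measured, 17 were higher and 1 lower, led by Fst (log2 2.66), Adipoq (2.08), Cxcl12 (1.57) and Lpl (1.56). Blood niche factor genes were higher in B (median log2 0.81, adjusted p = 0.00314, 0.164 with estimated correlation). Of 19 measured, 13 were higher and 3 lower, led by Cxcl12 (log2 1.57) and Ptn (1.50). Interferon response genes were higher in B (median log2 0.40, adjusted p = 0.0287, 0.367 with estimated correlation), a call lost without any 1 of A replicate 2 or B replicates 3 and 4 (adjusted p 0.0528 to 0.0952), and adjusted p = 0.241 with B and AB from replicates 1 and 2 and 0.109 with the neutrophil covariate. Of 14 measured, 4 were higher, led by Ifit2 (log2 1.06).

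Of the lists lower in AB than in A, all but the cell cycle list (median log2 -0.25, camera adjusted p = 0.118, but 0.0125 without B replicate 4, 0.00216 with B and AB from replicates 1 and 2, 0.0049 without every replicate 4 and 8.48e-05 with the neutrophil covariate) were lower in B too. Chondrocyte genes were lower in B (median log2 -1.54, adjusted p = 3.82e-14, 0.108 with estimated correlation). Of 21 measured, 20 were lower, led by Col10a1 (log2 -3.51) and Epyc (-3.29). Schwann cell genes were lower in B (median log2 -1.73, adjusted p = 3.09e-09, 0.102 with estimated correlation). Of 11 measured, 9 were lower (11 lower over the list alone), including Cdh19 (log2 -2.75) and Erbb3 (-2.47). Mature osteoblast genes were lower in B (median log2 -0.83, adjusted p = 8.68e-06, 0.0603 with estimated correlation). Of 17 measured, 2 were higher and 12 lower, led by Slc13a5 (log2 -2.59) and Car3 (-2.42). Tissue dissociation response genes were lower in B (median log2 -0.75, adjusted p = 6.5e-11, 0.259 with estimated correlation). Of 26 measured, 23 were lower (24 lower over the list alone), led by Egr2 (log2 -1.24). Glycolysis genes were lower in B (median log2 -0.71, adjusted p = 7.34e-07, 0.108 with estimated correlation). Of 13 measured, 9 were lower, led by Hk2 (log2 -1.83). Skeletal muscle genes were lower in B (median log2 -1.40, adjusted p = 0.0138, 0.0939 with estimated correlation). Of 3 measured, 2 were lower, led by Tnni2 (log2 -2.06) and Tnnt3 (-1.40). The chondrocyte score of B replicates 1 to 4 was -1.15, -0.78, -0.08 and -0.18, the Schwann cell score -0.82, -0.85, -0.02 and -0.24, and the pericyte score 1.39, 1.52, 0.67 and 0.49. No blood cell list was called for this pair in the main model. Some other settings called erythroid (median log2 0.67, adjusted p = 0.267, but 0.0248 with the replicate block), neutrophil lineage (median log2 0.59, adjusted p = 0.0745, but 0.0148 to 0.0389 without any 1 of A replicate 4 or B replicates 1 and 2, 0.00885 with the replicate block and 0.0263 without every replicate 4) and monocyte and macrophage (median log2 0.63, adjusted p = 0.0926, but 0.03 to 0.0416 without A replicate 4 or B replicate 2, 0.0115 with the replicate block and 0.0183 without every replicate 4) as higher in B.

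AB and B differ in the PDGFRa gate among PDGFRb-positive cells. Marrow stromal genes were higher in AB, among 139 genes that differed (102 higher, 37 lower). Esm1 rose from 4.84 ± 0.41 in B to 7.78 ± 0.58 in AB, a difference of 2.94 ± 0.21 (adjusted p = 7.7e-08), and Adipoq rose by 2.50 ± 0.29. Serpina3g rose by 2.85 ± 0.19, Cbln1 by 2.48 ± 0.23, the complement gene C6 by 2.32 ± 0.24, Shisa3, a regulator of Wnt and FGF receptors, by 2.28 ± 0.29 and Pappa, a protease that frees insulin-like growth factors, by 2.10 ± 0.21 (adjusted p at most 0.000132). Kcnj8 fell by 1.96 ± 0.28 (adjusted p = 0.000466), Tinagl1 by 1.43, Art3 by 1.39, the pericyte adhesion molecule gene Mcam by 1.33, Sncg by 1.22, Gas2 by 1.04 and Tspan15 by 1.04. The drug exporter gene Slc47a1 was higher by 2.55 ± 0.54 (adjusted p = 0.014), a call lost without B replicate 2 or AB replicate 2 (adjusted p 0.0555 to 0.0636). The collagen gene Col22a1 was lower by a log2 difference of -1.06 ± 0.25 (adjusted p = 0.0381), a call lost without any 1 of B replicates 1, 2 and 3 or AB replicates 1, 2, 3 and 4 (adjusted p 0.0555 to 0.161).

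With the replicate number as a block, 321 genes differed between AB and B, and the count was 79 without AB replicate 2 and 70 with these 2 groups alone, where Gas2 (adjusted p = 0.125), Mcam (0.117) and Sncg (0.0874) did not pass. Marrow stromal reticular genes were higher in AB (median log2 1.05, adjusted p = 9.36e-48, 0.000811 with estimated correlation). Of 24 measured, 19 were higher (23 higher over the list alone), led by Esm1 (log2 2.94), Adipoq (2.50), Lepr (1.92) and Gdpd2 (1.88). Blood niche factor genes were higher in AB (median log2 0.40, adjusted p = 6.35e-09, 0.0266 with estimated correlation). Of 19 measured, 8 were higher (10 higher over the list alone), led by Kitl (log2 1.50). Systemic bone regulator receptor genes were higher in AB (median log2 0.14, adjusted p = 0.000245, 0.0939 with estimated correlation). Of 15 measured, 3 were higher, led by Lepr (log2 1.92) and Esr1 (0.71, adjusted p 0.0618 with these 2 groups alone). Wnt pathway genes were higher in AB (median log2 0.10, adjusted p = 0.00648, 0.0792 with estimated correlation). Of 22 measured, 1 was higher (4 higher over the list alone). Adipocyte genes were higher in AB (median log2 0.07, adjusted p = 0.0321, 0.304 with estimated correlation), a call lost without any 1 of B replicates 1 and 2 or AB replicates 3 and 4 (adjusted p 0.0524 to 0.202), and adjusted p = 0.0901 with the replicate block and 0.0569 without every replicate 4. Of 9 measured, 2 were higher (3 higher over the list alone), led by Adipoq (log2 2.50) and Cebpa (0.95). Interferon response genes were higher in AB (median log2 0.20, adjusted p = 0.00792, 0.292 with estimated correlation), a call lost without AB replicate 4 (adjusted p = 0.0647). Of 14 measured, none passed (2 higher over the list alone). Lepr, the leptin receptor gene, which led the systemic receptor list, also belongs to the marrow stromal list.

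Vessel-wall and cartilage lists were lower in AB than in B. Pericyte and smooth muscle genes were lower in AB (median log2 -0.68, adjusted p = 1.29e-12, 0.0853 with estimated correlation). Of 14 measured, 2 were lower (10 lower over the list alone), led by Kcnj8 (log2 -1.96) and Mcam (-1.33, adjusted p 0.117 with these 2 groups alone). Chondrocyte genes were lower in AB (median log2 -0.45, adjusted p = 7.1e-10, 0.209 with estimated correlation). Of 21 measured, 1 was lower (9 lower over the list alone), led by Col10a1 (log2 -1.75, adjusted p = 0.514). Tendon and periosteum genes were lower in AB (median log2 -0.19, adjusted p = 6.13e-05, 0.164 with estimated correlation). Of 19 measured, 1 was lower (6 lower over the list alone). Schwann cell genes were lower in AB (median log2 -0.33, adjusted p = 0.0017, 0.367 with estimated correlation), a call lost without B replicate 3 (adjusted p = 0.0904), and adjusted p = 0.274 with B and AB from replicates 1 and 2 and 0.0669 with the neutrophil covariate. Of 11 measured, none passed (3 lower over the list alone). Cell cycle genes were lower in AB (median log2 -0.40, adjusted p = 4.12e-09, 0.25 with estimated correlation), but adjusted p = 0.0527 with the neutrophil covariate. Of 22 measured, none passed (2 lower over the list alone). Ribosomal protein genes were lower in AB (median log2 -0.11, adjusted p = 0.0451, 0.555 with estimated correlation), a call lost without any 1 of B replicates 3 and 4 or AB replicates 2 and 3 (adjusted p 0.115 to 0.326), and adjusted p = 0.0514 with the replicate block, 0.077 with quantile normalization, 0.845 with B and AB from replicates 1 and 2 and 0.972 at median log2 0.01 with the neutrophil covariate. Of 13 measured, none passed.

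Blood cell lists were lower in AB than in B as well, while none of their genes passed as lower in the main model. Neutrophil lineage genes were lower in AB (median log2 -0.71, adjusted p = 5.92e-08, 0.304 with estimated correlation, 0.509 with the neutrophil covariate by construction). Of 17 measured, none passed, led by Chil3 (log2 -1.06, adjusted p = 0.274, but 0.0101 with the replicate block and 0.023 without every replicate 4) and Mmp8 (-0.94, adjusted p = 0.383, but 0.0326 with the replicate block). Erythroid genes were lower in AB (median log2 -0.65, adjusted p = 2.34e-05, 0.304 with estimated correlation), but adjusted p = 0.354 with the neutrophil covariate. Of 11 measured, none passed. Monocyte and macrophage genes were lower in AB (median log2 -0.69, adjusted p = 0.00461, 0.456 with estimated correlation), a call lost without B replicate 4 (adjusted p = 0.0719), and adjusted p = 0.758 with the neutrophil covariate. Of 9 measured, 1 was higher (1 higher and 2 lower over the list alone), led by Vcam1 (log2 1.31) and Fcgr3 (-0.99, adjusted p = 0.304, but 0.0115 with the replicate block and 0.0489 without every replicate 4). B lineage genes were lower in AB (median log2 -0.51, adjusted p = 0.0483, 0.365 with estimated correlation), a call lost without any 1 of B replicates 1, 3 and 4 or AB replicates 2 and 3 (adjusted p 0.057 to 0.257), and adjusted p = 0.0521 with quantile normalization, 0.0707 with B and AB from replicates 1 and 2 and 0.886 with the neutrophil covariate. Of 4 measured, none passed, led by Fcrla (log2 -0.64, adjusted p = 0.586). Mast cell and basophil genes were lower in AB (median log2 -0.76, adjusted p = 0.0296, 0.183 with estimated correlation), a call lost without any 1 of B replicate 3 or AB replicates 1 and 3 (adjusted p 0.0502 to 0.109), and adjusted p = 0.16 with the neutrophil covariate. Of 3 measured, none passed (2 lower over the list alone), led by Mcpt8 (log2 -1.30, adjusted p = 0.381, but 0.0373 without every replicate 4). The neutrophil score of B replicates 1 to 4 was 0.46, 0.18, 0.94 and 1.28, and that of AB -0.07, -0.47, -0.27 and 0.92. In all, 17 lists were called in this pair, and other settings also called Sca-1-positive fibroblast (median log2 -0.02, adjusted p = 0.592, but 0.03 to 0.0454 without B replicate 2 or AB replicate 4 and 0.00424 at median log2 0.19 with the neutrophil covariate).

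**Figure D3:**
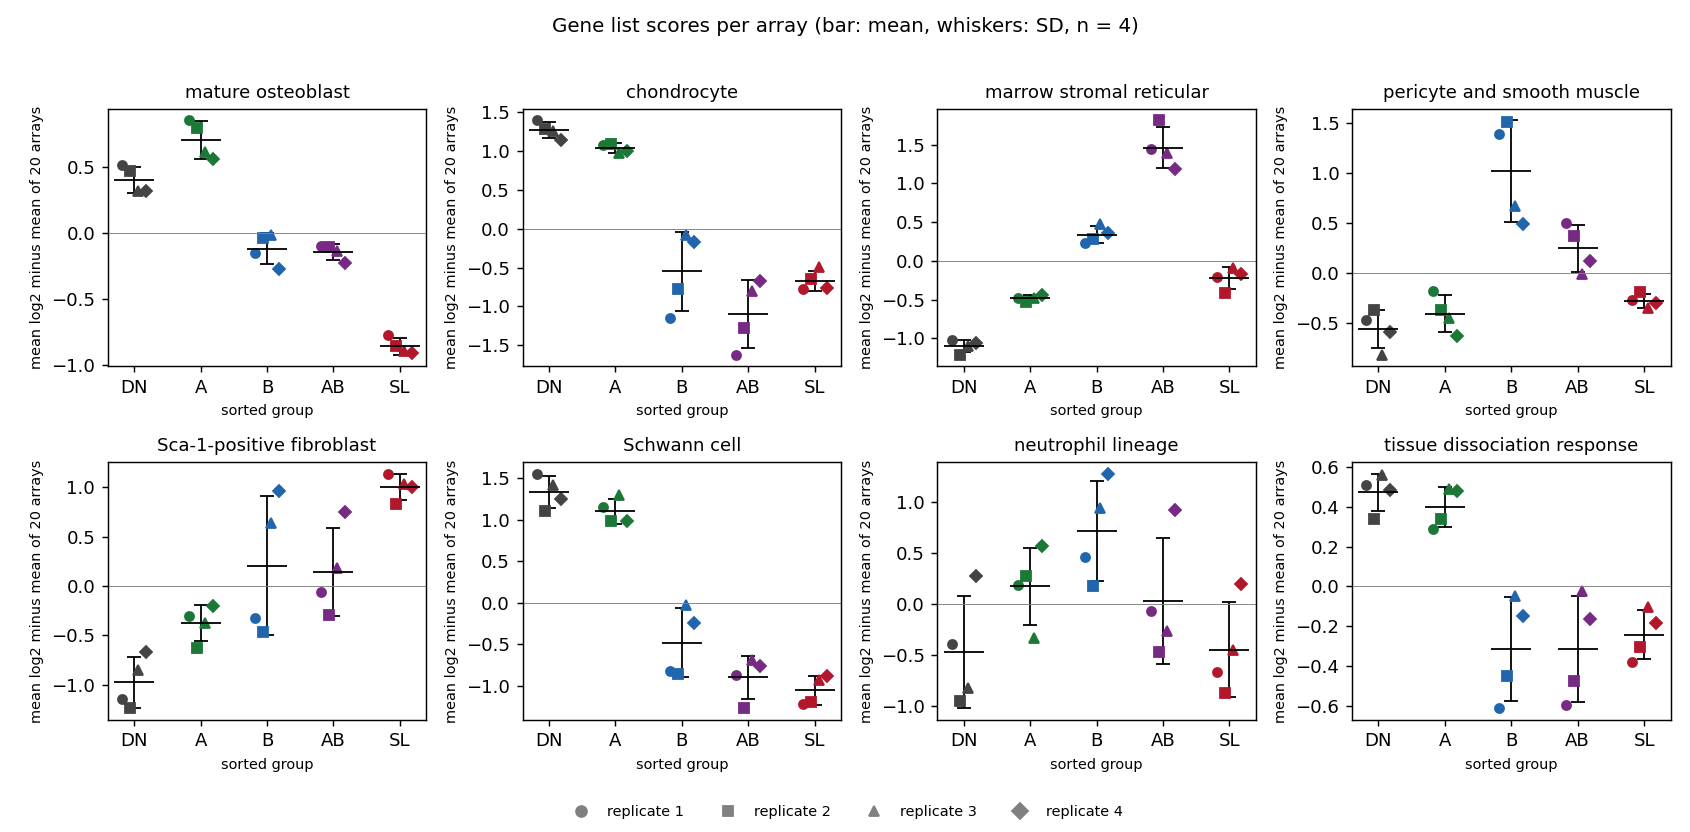
Score of selected gene lists in each array (points) and group means (bars), as the mean over members of log2 signal minus the gene's mean over 20 arrays. The marrow stromal reticular score is 1.46 ± 0.26 (SD, n = 4) in AB and -1.10 ± 0.08 in DN, and the chondrocyte score 1.27 ± 0.11 in DN and -1.09 ± 0.44 in AB.

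The 4 Sca-1-negative groups form a square of both receptors, in which the average difference along each receptor was tested. PDGFRb-positive groups averaged higher Cxcl12, the chemokine that holds blood stem cells in marrow, by 2.91 ± 0.13 and higher Adipoq by 4.05 ± 0.21, Fst by 2.75 ± 0.13, Ptx4 by 2.65 ± 0.20, Serpina3g by 2.63 ± 0.14 and Igfbp3, a carrier of insulin-like growth factors, by 2.58 ± 0.11. Serpina1b averaged -4.54 ± 0.47, Col10a1 -4.48 ± 0.60, Serpina1a -4.28 ± 0.21, Epyc -4.24 ± 0.26, Fxyd2 -3.83 ± 0.23 and Panx3 -3.74 ± 0.22. In all 4847 genes differed along PDGFRb (2623 higher, 2224 lower), against 334 along PDGFRa (257 higher, 77 lower), or 508 with the replicate block. Along PDGFRa, Slc47a1 averaged 2.25 ± 0.38, Shisa3 2.00 ± 0.21, Adipoq 1.97 ± 0.21, Dpep1 1.76 ± 0.20, Gpc3 1.72 ± 0.16 and Scara5 1.63 ± 0.37. Lower along PDGFRa were Serpina1a at -1.08 ± 0.21, Kcnj8 at -1.06 ± 0.20, Fxyd2 at -1.0 ± 0.23, Panx3 at -0.98 ± 0.22, Agbl4 at -0.92 ± 0.20 and Epyc at -0.95 ± 0.26 (adjusted p = 0.0466). The call of Epyc was lost without any 1 of DN replicates 1, 2, 3 and 4, A replicates 1, 3 and 4, B replicates 3 and 4 or AB replicates 1, 2 and 3 (adjusted p 0.0533 to 0.104), and without every replicate 4 also those of Fxyd2 (adjusted p = 0.0769), Panx3 (0.0892) and Agbl4 (0.063).

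The interaction test asked whether the PDGFRa difference changed with PDGFRb, and 61 genes passed (21 higher, 40 lower in AB minus B than in A minus DN). Esm1 differed by 2.79 ± 0.30 (adjusted p = 6.6e-05), Serpina3g by 2.63 ± 0.27, Cbln1 by 2.59 ± 0.32, C6 by 2.56 ± 0.35 and Pappa by 2.18 ± 0.30. Negative interactions were found for Col22a1 at -2.03 ± 0.36, Rasgrp2, an activator of Rap1, at -1.96 ± 0.23, the cell-adhesion protein vitronectin, Vtn, at -1.87 ± 0.33 and the fat-cell regulator gene Ebf2 at -1.80 ± 0.30. C1s1 differed by -2.11 ± 0.43 (adjusted p = 0.023), a call lost without any 1 of DN replicate 2 or A replicates 1 and 4 (adjusted p 0.0514 to 0.0597). Agt, the angiotensin precursor gene, differed by 1.51 ± 0.32 (adjusted p = 0.0309), a call lost without any 1 of DN replicates 1, 2 and 3, A replicates 1, 2 and 4, B replicates 1 and 2 or AB replicates 1 and 2 (adjusted p 0.0519 to 0.0784). The call of Kcnj8 at -1.79 ± 0.40 (adjusted p = 0.04) was lost without any 1 of DN replicates 1, 2, 3 and 4, A replicates 1, 2 and 4, B replicates 1 and 2 or AB replicates 2 and 3 (adjusted p 0.0579 to 0.105). With the neutrophil covariate those of Col22a1 (adjusted p = 0.052), Ebf2 (0.0595), C1s1 (0.0625) and Agt (0.145) ended. Across genes the PDGFRb differences with and without PDGFRa, taken from separate arrays, correlated at r = 0.867, with 2551 genes called in both in the same direction where independent lists would share 689.9. The PDGFRa differences correlated at r = 0.132, with 33 shared genes against 3.2. Genes are not independent replicates, so no p is given for either correlation. The count of interactions was 24 to 152 with 1 array left out, 360 with the replicate block, 156 without every replicate 4 and 26 with the neutrophil covariate.

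AB differed from DN in 4210 genes and B from DN in 4172, near the count of SL against DN. SL differed from A in 2976 genes, from B in 1138 and from AB in 853, or 1309 with array weights.

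**Figure D4:**
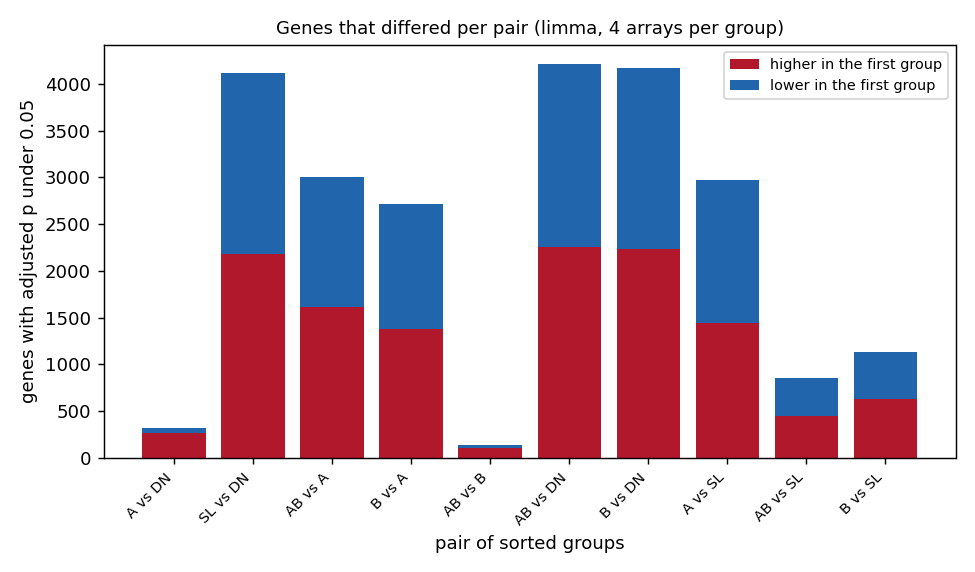
Number of genes higher and lower at limma adjusted p under 0.05 for each pair, out of 9129 tested. The smallest counts are 139 for AB against B and 322 for A against DN.

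302 genes were higher in 1 group than in each of the other 4, and 515 with the replicate block. SL had 171 of them, AB 56, DN 56, B 15 and A 4. In SL these were led by Ret, the GDNF co-receptor gene, at log2 2.20 above the next group, Clec3b at 1.99, the cortisone-reducing enzyme gene Hsd11b1 at 1.91, Lgi2 at 1.82, Inmt at 1.79 and the angiopoietin receptor gene Tek at 1.75. AB was led by Esm1 at 2.94, Serpina3g at 2.85, Adipoq at 2.50, Cbln1 at 2.48, C6 at 2.32 and Pappa at 2.10. The 4 genes of A were Car3 at 1.92, Tenm2 at 1.10, Cpz at 0.83 and the osteoblast membrane protein gene Ifitm5 at 0.64. B was led by Kcnj8 at 1.96, Sncg at 1.22, Gas2 at 1.04, the vessel-wall connexin gene Gja4 at 1.04, the laminin receptor gene Itga7 at 0.97 and Tinagl1 at 0.90. DN was led by Serpina1a at 1.14, Bdkrb1 at 0.93, Agbl4 at 0.93, Phxr4 at 0.93, Zim1 at 0.83 and Prss50 at 0.82.

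Some of these genes were no longer highest when 1 array was left out, given here with the highest adjusted p against the other 4 groups. In SL this held for Clec3b without any 1 of DN replicates 1, 2, 3 and 4, A replicates 1, 2, 3 and 4, B replicates 1 and 2, AB replicates 1, 2 and 3 or SL replicates 1, 2, 3 and 4 (adjusted p 0.0506 to 0.174), Inmt without any 1 of AB replicates 1, 2 and 3 or SL replicates 1, 3 and 4 (adjusted p 0.0594 to 0.0939) and Tek without any 1 of B replicates 1 and 2 or SL replicates 1 and 3 (adjusted p 0.0675 to 0.0939). In B it held for Gja4 without any 1 of B replicates 1, 2 and 3 or AB replicates 2, 3 and 4 (adjusted p 0.0768 to 0.116), Itga7 without any 1 of B replicates 1 and 2 or AB replicates 1, 2, 3 and 4 (adjusted p 0.0657 to 0.131) and Tinagl1 without B replicate 1 or 2 (adjusted p 0.0636 to 0.0689). In DN it held for Agbl4 without B replicate 3 (adjusted p = 0.0551), Phxr4 without any 1 of DN replicates 2 and 3 or A replicates 1 and 4 (adjusted p 0.0624 to 0.092) and, with the same arrays and adjusted p as for A against DN, Bdkrb1, Serpina1a, Zim1 and Prss50. With the neutrophil covariate Agbl4 fell to 0.49 above the next group (adjusted p = 0.294), and with B and AB from replicates 1 and 2 Ifitm5 did not pass as highest in A (adjusted p = 0.0724).

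The authors' deposited tables of the same 5 pairs list 1 probe set per gene with a log2 difference and a q-value. At q under 0.05 the authors' deposited table of DN against A holds 211 of 8243 genes and that of DN against SL 5253 of 8513. The authors' deposited tables of A against AB, A against B and B against AB hold 3815, 3213 and 88.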

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

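All tests of the 3 patterns weighed first were chosen after the patterns were seen, and the single-array marks and interaction tests that follow were fixed before. Ly6a was higher in replicates 3 and 4 than in 1 and 2 of B and AB, by log2 3.49 and 2.22, while DN, A and SL differed by at most 0.76, which argues against a shift of those numbers in every group. A mislabelled SL array was excluded, since in 4 of 4 arrays the upper quartile of the SL share over other genes high in SL was under 100%. Sca-1-low cells mixed into these arrays cannot be told apart from another source of Ly6a, since the median SL share over genes high in SL was 27.1%, 41.6%, 10.9% and 29.5% where Ly6a needed 77.7%, 134%, 21.2% and 69.9%, and 1 of 4 arrays met the bound set for a mixture. Such cells were excluded as the source of the chondrocyte list in B, which lay at least log2 0.32 above every SL array in replicates 3 and 4. Lower purity of B and AB in these arrays may account for the pattern, since 6 of 6 shifts went as it needs (chondrocyte and Schwann cell lists up, own list down), and a biological difference between the animals sorted was not tested.

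Neutrophil genes were highest in replicate 4 of every group. Carry-over of blood cells past the lineage depletion may account for it, since the erythroid and the monocyte and macrophage lists were highest in replicate 4 in 10 of 10 combinations of list and group. Apart from the replicate number, the PDGFRb single-positive gate could hold more blood cells, since the neutrophil list was highest in B among the Sca-1-negative groups at 3 of 4 replicate numbers. Vcam1 is shared with stroma, and both processes remain open for the blood lists of B.

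Uchl5 varied widely within A, B and AB, from 3.83 to 10.08 in A. It was higher in replicates 3 and 4 than in 1 and 2 of A and AB, and in B replicate 3 but not 4 (10.24 and 3.91), which are the numbers of the Ly6a pattern, although Ly6a differed by log2 0.16 in A. Whether both share a cause was not tested. SL-type cells were excluded as the source in A, since the upper quartile of the SL share over genes high in SL was at most 13% in A replicates 3 and 4, where Uchl5 needed 192% and 151%. A factor shared with other genes may account for it, since 74 genes correlated with Uchl5 within groups beyond 0.8 in absolute r, against at most 41 in 100 draws with the arrays shuffled, so that 0 draws gave as many. Genes are not independent replicates, and neither a probe artifact nor a biological cause was tested.

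Of 830 combinations of a named gene or list with a group of 4 arrays, 43 held 1 array beyond Dixon's critical gap from the other 3, where chance gives about 1 in 20 (41.5). In log2 signal for genes and mean centred log2 for lists, these were A replicate 1 (Lpl 9.71, blood niche factors list -0.19, Wnt pathway list 0.06), A replicate 2 (Dpep1 7.07, Serping1 10.56), A replicate 3 (Chil3 9.87, Pdgfra 9.15, Top2a 7.64, osteoclast regulators list -0.10), A replicate 4 (Procr 7.36), AB replicate 2 (Gpc3 9.66, Igfbp3 8.85, Ms4a4d 8.84), AB replicate 3 (Muc1 7.15, oxidative phosphorylation list -0.18). Further values of this kind stood in AB replicate 4 (Mfap5 9.85, Mmp8 8.93, Pdgfra 9.54, Pdgfrb 10.46, monocyte and macrophage list 1.05, Wnt pathway list 0.14), B replicate 1 (Gas2 7.72, Muc1 5.66, Serpina1b 4.07, Tnnt3 6.09), B replicate 2 (Rasgrp2 7.50), B replicate 3 (Uchl5 10.24), DN replicate 1 (Ptx4 6.12, tendon and periosteum list -0.43), DN replicate 2 (Gas2 4.40, Tspan15 5.63). The remaining ones were in DN replicate 4 (Esr1 8.02, Pecam1 7.38, Slc36a2 7.38), SL replicate 1 (Elane 8.00, Esr1 8.64), SL replicate 2 (Esm1 3.80, Rasgrp2 5.12, adipocyte list -0.34), SL replicate 3 (Cpz 6.42, Itgav 9.62, Sfrp4 10.27), SL replicate 4 (osteocyte list -0.11).

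The PDGFRa difference changed with PDGFRb in 61 genes by limma's interaction test. Of the named genes, those with a larger log2 difference in AB minus B were Agt 1.51, C6 2.56, Cbln1 2.59, Esm1 2.79, Pappa 2.18, Serpina3g 2.63 and Vegfc 1.43. Those with a smaller one were Adamts2 -0.65, Angptl7 -1.52, Apod -1.34, Art3 -1.06, C1s1 -2.11, Car3 -1.55, Col22a1 -2.03, Cpz -1.28, Ebf2 -1.80, Kcnj8 -1.79, Rasgrp2 -1.96, Serping1 -0.88, Thy1 -1.57, Tspan15 -1.33 and Vtn -1.87. In data outside the comparisons, 2065 of the 12099 probe sets outside the filtered table, which carry no gene symbol in the files, differed among the 5 groups by limma's F test.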

How the results depend on the processing

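The adjustment over all probe sets, the restriction of B and AB to replicates 1 and 2, the removal of every replicate 4 and the neutrophil covariate were chosen after the data were seen, and the other alternatives before. Signal over background was not measured, so a gene near the lowest signals may have a compressed difference and a missing call says little. Leaving out 1 array in turn gave 179 to 302 genes for A against DN (main count 322, with 179 without A replicate 4 and 196 without A replicate 1) and 79 to 194 for AB against B (main count 139, with 79 without AB replicate 2). For the interaction it gave 24 to 152 (24 without A replicate 1, 34 without A replicate 4, 36 without B replicate 1, 39 without B replicate 2, 31 without AB replicate 2, 152 without AB replicate 4), against 61 with all arrays. The other counts stayed within 1.5 times the main count, at 3679 to 4007 for SL against DN, 2522 to 2990 for AB against A, 2252 to 2784 for B against A, 3783 to 4157 for AB against DN, 3717 to 4092 for B against DN, 2518 to 2881 for A against SL, 598 to 877 for AB against SL and 832 to 1090 for B against SL. They were 263 to 350 along PDGFRa, 4589 to 4855 along PDGFRb, 4361 to 4678 among the 5 groups, 241 to 321 for genes highest in 1 group and 66 to 79 for list calls.

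With the replicate number as a block, 546 genes differed between A and DN, 321 between AB and B, 360 in the interaction and 508 along PDGFRa, and 515 were highest in 1 group. Of the 180 list tests, the block lost 3 calls and added 11. With array weights AB and SL differed in 1309 genes. With only the compared groups in the model the counts were 167 for A against DN and 70 for AB against B, where fewer arrays estimate the spread. With an absolute log2 difference above 1 also required, which by construction can lower a count and not raise it, the counts were 55 for A against DN, 975 for SL against DN, 664 for AB against A, 597 for B against A and 59 for AB against B. On the same terms they were 1075 for AB against DN, 1074 for B against DN, 597 for A against SL, 199 for AB against SL, 358 for B against SL and 1557 among the 5 groups. The interaction and the PDGFRa average then had 37 and 37, the PDGFRb average 814 and the genes highest in 1 group 66. Adjusted over all probe sets, 36 genes passed the interaction. Without replicate 4 of every group, A and DN differed in 192 genes and the interaction had 156. The cause was not tested for these changes, apart from those that follow from how a setting was made.

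With the neutrophil score of each array as a covariate, the interaction had 26 genes. The direction of camera, which sets a list against the other genes, turned for A against DN at median log2 -0.2318 for the erythroid list (adjusted p = 0.0416), -0.1528 for the monocyte list, -0.1741 for the cell cycle list (adjusted p = 0.00375) and 0.0456 for the neutrophil list, which the covariate removes by construction and whose median kept its sign. For AB against B it turned at 0.1874 for the Sca-1-positive fibroblast list (adjusted p = 0.00424), -0.023 for the monocyte list, whose median kept its sign, and 0.0103 for the ribosomal list. Those with a p here became calls in the new direction, and the others did not pass. Ptprc turned to -0.353 for B against DN and -0.1524 for B against SL. Of the named calls lost when 1 array was left out, these were also lost without every replicate 4, Serpina1a, Bdkrb1, Zim1, Muc1, Ckb, Lepr and Pdgfrb (A against DN), C1s1 (interaction), Epyc (PDGFRa average) and Phxr4 (highest in DN). Lost with the covariate were Scara5, Zim1, Prss50, Ckb, Lepr, Sfrp4 and Vcam1 (A against DN), Col22a1 and Pdgfra (AB against B), Agt and C1s1 (interaction) and Phxr4 (highest in DN), with the compared groups alone Zim1, Gnat2, Ckb, Kcnk2 and Vcam1 (A against DN) and Slc47a1, Col22a1 and Pdgfra (AB against B) and with B and AB from replicates 1 and 2 Col22a1 (AB against B), C1s1 (interaction) and Ckb and Vcam1 (A against DN). With the compared groups alone Ctsk in A against DN did not pass either (adjusted p = 0.0835). With the correlation estimated per list, 3 of 72 list calls held. Quantile normalization and centring arrays on their median moved no count by over 1.5 times, and lost 2 and 2 calls of named genes, the former also 3 of lists. Trend and robust moderation, probe sets above the median of all, every probe set tested and the values of the filtered table moved no count by over 1.5 times. No value was had for the unfiltered series table, whose other probe sets carry no gene symbol, or a pseudocount, since values were already log2.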

Other observations

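Gene lists of several kinds passed as a set in no main pair, given here with the number of measured genes and the lowest camera adjusted p of the 5 pairs. Among cell types these were the lists of osteoblast commitment (18 genes, 0.0585 in SL against DN), endothelium (4 genes, 0.184 in SL against DN), megakaryocytes and platelets (6 genes, 0.137 in AB against B) and T and NK cells (2 genes, 0.0877 in A against DN), the last through Thy1, which stromal cells also carry. Among pathways they were BMP and TGF-beta (26 genes, 0.135 in AB against B), hedgehog and Notch (13 genes, 0.112 in B against A), the unfolded protein and secretory pathway (25 genes, 0.0569 in B against A) and oxidative phosphorylation (25 genes, 0.118 in AB against B). The sorted surface markers (6 genes, 0.0585 in A against DN) did not pass either. Leaving out 1 array or another setting let some pass. The gate markers passed for A against DN without DN replicate 4 or A replicate 3 (adjusted p 0.0102 to 0.0375), with B and AB from replicates 1 and 2 (0.0238), or without every replicate 4 (0.0134) and for SL against DN without DN replicate 4 (adjusted p = 0.0314), with B and AB from replicates 1 and 2 (0.0294), or without every replicate 4 (0.0294). Osteoblast commitment passed for SL against DN without any 1 of DN replicates 3 and 4 or SL replicates 2 and 4 (adjusted p 0.0363 to 0.049), with the replicate block (0.0459), or without every replicate 4 (0.0278) and for A against DN with the neutrophil covariate (adjusted p = 0.0394). The unfolded protein list passed for AB against A without any 1 of A replicates 3 and 4 or AB replicate 1 (adjusted p 0.0275 to 0.0416) and for B against A without any 1 of A replicates 3 and 4 or B replicate 1 (adjusted p 0.0294 to 0.0416), with the replicate block (0.048), or without every replicate 4 (0.0446). Oxidative phosphorylation passed for A against DN without A replicate 3 (adjusted p = 0.00654), for B against A without A replicate 1 (adjusted p = 0.0465) and for AB against B without B replicate 2 or AB replicate 4 (adjusted p 0.03 to 0.0408).

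Other splits of the same arrays into groups of the same sizes, a test fixed before, were counted for each count of genes. For 9 of the 10 pairs the real split alone of 35 gave as many genes, so chance can be excluded for them. The highest count of another split was 3 for A against DN (real 322), 2 for SL against DN (real 4122), 0 for AB against A (real 3004), 522 for B against A (real 2714) and 7 for AB against DN (real 4210). It was 567 for B against DN (real 4172), 0 for A against SL (real 2976), 0 for AB against SL (real 853) and 1 for B against SL (real 1138). For AB against B, 2 of 35 splits gave as many genes. The split of lowest neutrophil scores, AB replicates 1, 2 and 3 with B replicate 2, gave 179 beside 139. So the test cannot decide on chance there. Of 8 splits parting every replicate number, the real one was highest and the next gave 0. Yet 8 are too few for a share under 0.05.

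Of 100 drawn splits of the 20 arrays, the real one included, 1 gave as many genes among the 5 groups (4620 against at most 2164 otherwise), 1 as many highest in 1 group (302 against 10), 1 as many along PDGFRb (4847 against 3315) and 1 as many list calls (72 against 65). Chance can be excluded for these 4 counts, although other splits also call many lists, so a list call by itself separates these groups poorly from other partings of the arrays. Along PDGFRa 4 of 100 splits gave as many (334 against at most 2455), and for the interaction 4 of 100 did (61 against at most 3565). A share of 4 in 100 draws is too imprecise to exclude chance for these 2. Splits that mix PDGFRb states can also carry its difference into these counts, so the test cannot decide.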
